A study of Homo sapiens with 2 samples.

How the data were processed

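Human cells were profiled by droplet single-cell RNA sequencing with a Chromium 3' kit. Cardiac progenitor cells had been differentiated from the WTC-CAAX-RFP line and epicardial cells from the WTC-LMNB1-eGFP line, which are established human induced pluripotent stem cell lines with constitutive fluorescent reporters. Per the labels, the coculture library holds cells grown together for 14 days and the monoculture library holds cells grown apart. Live cells were gated by exclusion of the dye DAPI. The ratio in which the separately grown cells were combined is not given in the sources used here. The labels give no time in culture for the cells grown apart. Each group has 1 library, so the design has no replicates.

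The deposited matrices hold raw UMI counts per gene and cell barcode, whole numbers with no normalization. Per the file headers and the submitters' processing notes, the authors made these counts with Cell Ranger 4.0.0 on the genome build GRCh38, and the barcodes are those which that program called cells. The matrices have 36603 features, of which the last 2 are named GFP and RFP. The annotation release is not given in the sources used here, so genes are named by the symbols and identifiers of the deposited feature list and no coordinates are given. Y-linked genes and XIST were left out of every result. Close copies such as MYH6 and MYH7, or the members of the IFITM and HSPA1 families, can share reads, and how the authors' counting split these is not given in the sources used here, so their values are less certain.

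The labels state about 390 M reads per library, about 71000 reads per cell and an estimated 6000 cells loaded. The stated reads over the stated depth imply 5493 cells. The matrices hold 5464 barcodes in the monoculture library and 7142 in the coculture library, and the stated reads over these barcodes give 71376 and 54607 reads per barcode. UMI totals were 140613582 and 178707695. The lowest total of any barcode was 501 UMIs in the monoculture library and 500 in the coculture library.

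Barcodes with fewer than 1000 detected genes or more than 30% mitochondrial UMIs were removed. Doublets were scored per library with Scrublet through scanpy. Its automatic threshold marked 0.0431% of the monoculture barcodes and 0% of the coculture barcodes, so it had not worked, and the highest scores were removed at 0.8% per 1000 barcodes instead. This took out 203 and 390 barcodes. The cells used were 4442 in the monoculture library and 6433 in the coculture library.

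Both libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen within libraries without cell cycle, mitochondrial and ribosomal genes, and 30 principal components and 15 neighbours were used. Leiden clustering at resolution 0.5 gave 17 clusters. Marker lists for 10 cell types were fixed before the data were examined, as were the function lists, the filters, the named-gene rule and most of the alternatives. The epicardial, fibroblast and mural marker lists were merged into an epicardial-lineage class. The rule that turns markers into cluster names was set after the clusters were seen. A marker counted when at least 25% of the cluster's cells held it at 1.5 times or more the level in other cells, and the class with the most such markers gave the name if it had at least 3. A cluster stayed unnamed where its 10 leading genes held more markers of another class, or where its median depth was under 1/3 of its libraries' and its 10 leading genes held no marker of its own. Cluster 14 had 14 of 62 epicardial-lineage markers higher but 0 of them among its 10 leading genes, against 1 cardiomyocyte marker, SLN. Cluster 16 had 16 higher, 0 among its leading genes, and a median depth of 0.167 of its libraries'. Both were left out of the epicardial-lineage-like class for these reasons. No cluster took a neural, pluripotent, immune or skeletal myogenic name. The study's own cell annotation was not used, and a difference from the study may come from these rebuilt names.

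Counts were summed over the cells of a class in each library and expressed as CPM, the count scaled to the class sum. The ratio of coculture over monoculture was taken on the log2 scale with 0.5 counts added to each sum. Sums carry exact Poisson 95% intervals, shares carry exact Clopper-Pearson 95% intervals and ratios carry exact conditional intervals. All of them cover counting error only. Those of sums and ratios take UMIs as independent and leave out the spread between cells. They are too narrow where few cells hold most of a gene's UMIs. No test between the libraries was made and no p-value is given. A list's median was taken over members at 10 CPM or more in either sum, with an interval from 500 Poisson draws. Its percentile among 10000 random lists of the same size, matched on mean expression, describes these libraries alone. Members count as higher or lower at a ratio of at least 1.5, which is a size rule.

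The median log2 ratio of all genes was 0.07 in cardiomyocyte-like cells, 0.02 in endoderm-like cells and -0.24 in epicardial-lineage-like cells. Log2 values of epicardial-lineage-like cells are therefore given relative to that shift, so 0 means a gene that follows the class median. CPM values are raw in every class.

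The 30 function lists cover S phase, G2/M phase, core mitotic genes, cell cycle inhibitors, ventricular, atrial and pacemaker genes, cardiac transcription factors, sarcomere, calcium handling, ion channels, cell junctions, oxidative phosphorylation, fatty acid oxidation, glycolysis, hypoxia response, cholesterol synthesis, immediate early and heat shock genes, p53 targets, extracellular matrix, epicardial identity, mesenchyme genes, smooth muscle contractile genes, retinoic acid genes, growth factors, and targets of TGF-beta, BMP, YAP, Wnt and interferon signalling. Named genes follow a fixed rule. In each class they are the 12 genes highest and the 12 lowest in the coculture library among genes at 100 CPM or more in either sum, which had to reach 25% of the level in the other class. Mitochondrial, ribosomal, HLA and unnamed transcripts were left out. Up to 4 members of each list at 50 CPM or more with the largest ratios were added, and a fixed set of cell cycle, cardiac and epicardial genes was named whatever its value. Endoderm-like cells were not foreseen when the rule was written, and their genes were picked by the same rule after the class appeared.

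A cell was called RFP-positive at 3 or more RFP UMIs and RFP-zero at none. Shares of cells with a transcript were compared after each cell was thinned to 5000 UMIs, leaving out shallower cells. Free RNA in a class sum was estimated from 5 endoderm transcripts (AFP, APOA1, APOA2, TTR and FGB).

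Alternatives chosen beforehand were no cell filter, at most 15% mitochondrial UMIs, doublets kept, Leiden resolution 1, assignment of each cell by its own markers, median-ratio scaling, the mean of single-cell CPM, free RNA subtracted, list members at 50 CPM or more, all members with a count, thinning to 3000 UMIs, no thinning, and at least 3 core mitotic genes in place of 2. Runs with no cell filter, over all deposited barcodes, put the marked doublets back too. Assignment by RFP, no cell filter with the unnamed clusters of most cardiomyocyte markers added to the class, removal of class cells under 5000 UMIs, removal of the low-UMI cardiomyocyte-like cluster and removal of the cycling cluster from the epicardial-lineage-like class (cluster 8) and from the cardiomyocyte-like class (cluster 12, the one with the highest MKI67) were chosen after seeing the data.

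The steps were tested on simulated counts with 200 changed genes per fold. These counts were Poisson draws of class sums, the spread that the intervals assume, so a coverage near 95% was built in. Spread between cells and genes that rise together in the same cells were not simulated. For the cardiomyocyte-like comparison, on 8884 genes, the right sign was found for 99.0% of genes changed 1.5-fold and for 100% of those changed 2-fold or 4-fold. The size rule recovered 48.0%, 98.0% and 100% of them, where a true 1.5-fold lies on its edge, and 95.8%, 95.6% and 95.9% of intervals covered the truth. For the epicardial-lineage-like comparison, on 9041 genes, the sign was right for 100% at each fold. The size rule recovered 50.0%, 100% and 100%, and 95.2%, 95.4% and 95.2% of intervals covered the truth. In the 2-fold run 20 random lists were drawn from all genes tested, so they could hold changed ones. Of these, 2 fell outside the middle 95% in the former comparison and 0 in the latter.

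The software was Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.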

Results

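RNA was counted in cells from 2 human libraries. The monoculture library held cardiac progenitor-derived cells and epicardial cells that had been grown apart, and the coculture library held both kinds after 14 days in direct contact. With 1 library per group there were no replicates, so every difference below compares these libraries and not the conditions. The labels give no culture time for the cells grown apart, so the libraries cannot be taken as matched in age. The libraries are named as labelled, and the labels name no transcript by which the names could be checked. The monoculture library held 5464 barcodes with a median of 23803 UMIs and a median of 5213 genes. The coculture library held 7142 barcodes with medians of 22822 UMIs and 4841 genes. After filters and removal of marked doublets, 81.3% and 90.1% of barcodes were used. In the monoculture library 597 barcodes fell under the gene minimum and 584 exceeded the mitochondrial limit, against 231 and 175 in the coculture library.

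The cells formed cardiomyocyte-like, epicardial-lineage-like, endoderm-like and endothelial-like classes. Cardiomyocyte-like cells carried troponin, myosin and titin transcripts, epicardial-lineage-like cells carried WT1, collagens and keratins, and endoderm-like cells carried AFP, TTR and apolipoproteins. Cardiomyocyte-like cells made up 20.2% (95% interval 19.0 to 21.4%) of the monoculture cells, 898 of 4442, and 2.39% (2.03 to 2.80%) of the coculture cells, 154 of 6433. Epicardial-lineage-like cells made up 58.8% (57.3 to 60.2%) and 82.5% (81.6 to 83.4%), and endoderm-like cells 17.9% (16.8 to 19.1%) and 13.9% (13.1 to 14.8%). Endothelial-like cells, with PECAM1, CDH5 and KDR, made up 0.653% and 0.0622%, and 2.48% and 1.09% of cells stayed unnamed. The monoculture shares describe how the suspension was made up, and the ratio in which its parts were combined is not given in the sources used here. Assigning each cell by its own markers alone raised the cardiomyocyte-like share to 81.9% in the monoculture library and 34.5% in the coculture library. By clusters, only 24.6% and 6.90% of the cells so assigned were cardiomyocyte-like. Assignment by own markers divided each cell's cardiomyocyte and epicardial-lineage marker shares by their medians over all cells used, and took the larger. This scaling sets much of the shares it gives, so they do not count cardiomyocyte-like cells.

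**Figure D1:**
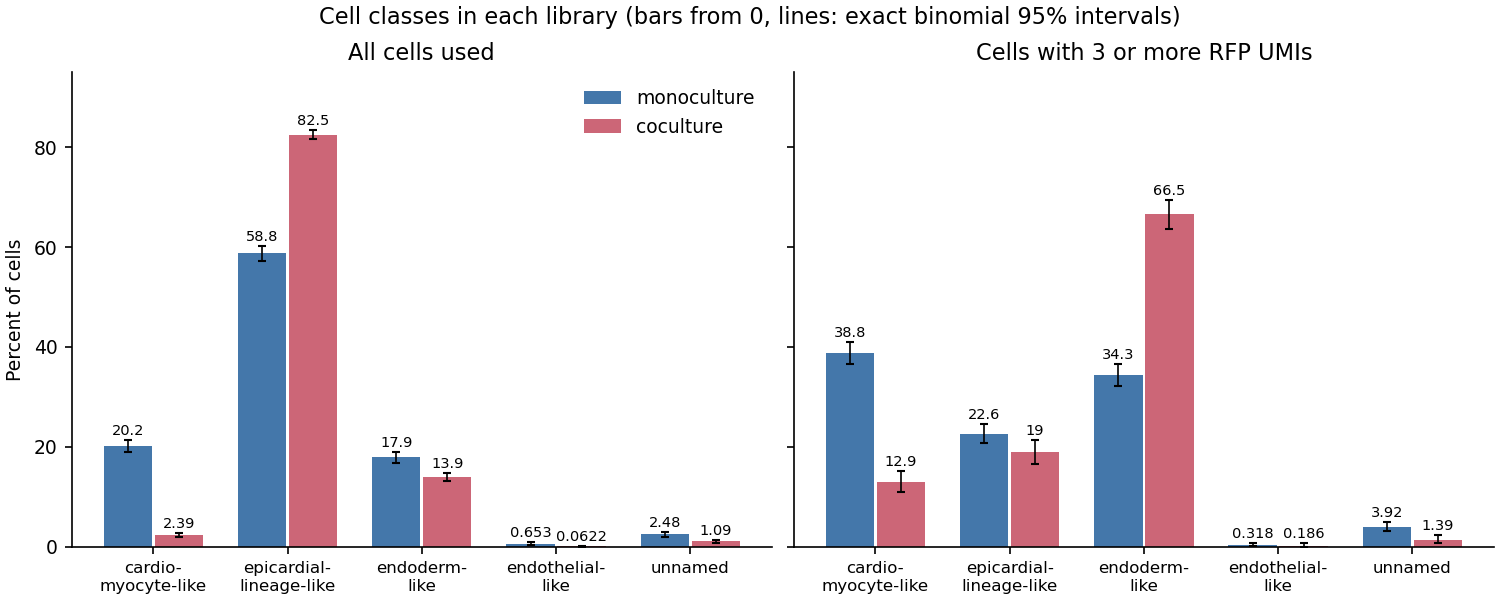
Percent of cells in each class (vertical axis, percent of cells; bars from 0, lines are exact binomial 95% intervals) in the monoculture and coculture libraries, over all cells used and over cells with 3 or more RFP UMIs. Cardiomyocyte-like cells made up 38.8% of the RFP-positive cells in the monoculture library and 12.9% in the coculture library.

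The RFP transcript marks the line from which the cardiac progenitors were made. It was found at 3 or more UMIs in 81.6% (78.9 to 84.1%) of monoculture and 90.3% (84.4 to 94.4%) of coculture cardiomyocyte-like cells, and in 16.4% and 3.84% of epicardial-lineage-like cells, at median depths of 19134, 16287, 25065 and 22023 UMIs. In cardiomyocyte-like cluster 6 it was found in 91.1% and 96.2% of cells. The low-UMI cluster 15 held 88 and 6 cells of that class, 9.80% and 3.90%. There RFP was found in 23.9% and 16.7%, at median depths of 3082 and 2288 UMIs. Its name rests on 1 marker, TCAP, among its leading genes. Endoderm-like cells were RFP-positive in 81.5% and 79.9% of cases, at median depths of 39159 and 33534 UMIs. RFP stood at 1011 CPM in the monoculture and 2187 CPM in the coculture cardiomyocyte-like sum. Among RFP-positive cells alone, 1888 and 1076 cells, cardiomyocyte-like cells made up 38.8% (36.6 to 41.1%) in the monoculture library and 12.9% (10.97 to 15.1%) in the coculture library. Endoderm-like cells made up 34.3% (32.2 to 36.5%) and 66.5% (63.6 to 69.4%) of them, and epicardial-lineage-like cells 22.6% and 19.0%.

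Whether cardiomyocytes cycled differently next to epicardial cells was read from mitotic and replication transcripts. In cardiomyocyte-like cells 16 of 51 measured G2/M genes were at least 1.5-fold lower in the coculture library, 0 were higher and 35 lay between. MKI67, which coats mitotic chromosomes, stood at 82.3 CPM in the monoculture and 47.7 CPM in the coculture library. The replication enzyme gene TYMS and the mitotic survival gene BIRC5 were lower too, while the mitotic kinase gene CDK1 did not differ detectably at this depth. The comparison sets 898 cells with 17.5 M UMIs against 154 cells with 2.45 M, and mitochondrial transcripts made up 13.2% and 8.16% of these UMIs. MKI67 had a log2 ratio of -0.78 (-1.07 to -0.52), TOP2A, which untangles replicated DNA, -0.42 (-0.65 to -0.20), and CCNB1, the cyclin of mitotic entry, -0.51 (-0.80 to -0.25). BIRC5 stood at 62.0 and 37.5 CPM, TYMS at 144 and 76.6 CPM, and CDK1 at 25.7 and 19.97 CPM with an interval of -0.82 to 0.06.

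The median log2 ratio of the G2/M list was -0.43 (-0.51 to -0.34), below all 10000 random lists, and 8 of its members lay above 0. The interval and the random lists take UMIs and genes as independent. Mitotic genes share cells, so both make this median look firmer than it is. The 10 core mitotic genes had a median of -0.58 (-0.73 to -0.41), with 5 lower and 5 between, and the 24 S phase genes one of -0.21 (-0.38 to -0.09), with 6 lower. The S phase median was -0.011 over all deposited barcodes, 0.027 with unnamed clusters of mostly cardiomyocyte markers added and -0.023 with doublets kept. After thinning to 5000 UMIs, 19.6% of monoculture and 6.77% of coculture cardiomyocyte-like cells held at least 2 core mitotic transcripts, a difference of -12.8 percentage points (-17.5 to -6.51). This left out 122 and 21 shallower cells, and without thinning the shares were 29.3% and 13.6%. Over all deposited barcodes the difference was -6.46 points with an interval of -11.8 to 0.23, and with unnamed clusters of mostly cardiomyocyte markers added -5.00 points (-10.01 to 1.19), and both intervals include 0. Both of these runs also put the marked doublets back. With doublets kept and the filters unchanged, the shares were 18.8% and 11.25%, a difference of -7.58 points (-12.8 to -1.10). The size of the difference therefore depends on the doublet removal. Among cell cycle inhibitors only the p53 target CDKN1A left the 1.5-fold band, at 57.2 and 14.7 CPM (log2 ratio -1.94, or -1.34 with doublets kept), and the list's median was -0.01 at percentile 28.1. The 11 p53 targets, many of which act in arrest or cell death, had a median of -0.44, with 4 lower and 7 between.

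Of the 1439 and 117 MKI67 UMIs of the class, 1246 and 95 lay in cluster 12. This cluster held 124 monoculture and 15 coculture cells, 13.8% (11.6 to 16.2%) and 9.74% (5.55 to 15.6%) of the class, shares whose intervals overlap, and 13.4% and 8.01% of its UMIs. MKI67 stood at 532 (503 to 563) and 483 (391 to 591) CPM in it. In cluster 6, which held 686 and 133 cells, MKI67 stood at 12.3 (10.6 to 14.2) and 9.81 (6.15 to 14.9) CPM and did not differ detectably. Within cluster 12, which rests on 15 coculture cells, 6 of 52 G2/M genes were higher, 1 lower and 45 between, with a median of 0.18 (0.039 to 0.23). Core mitotic genes there had a median of 0.19 (0.0062 to 0.32), with 1 of 10 higher, and S phase genes one of -0.37 (-0.72 to -0.19), with 15 of 39 lower and 3 higher. With cluster 12 left out, an alternative chosen after seeing the data, 5 of 29 G2/M genes were lower and 24 between, with a median of -0.12 (-0.28 to -0.025). Core mitotic genes then had a median of -0.80 (-1.04 to -0.39), with 4 of 7 lower, and the S phase median turned to 0.11 (-0.064 to 0.20). The thinned difference in cells with core mitotic transcripts was then -3.99 percentage points, with an interval of -7.89 to 1.85 that includes 0.

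Ventricular identity was the other question put to the cardiomyocyte-like cells. The ventricular light chain gene MYL2 was lower in the coculture library, at 786 and 132 CPM, and so were the slow ventricular myosin gene MYH7, at 549 and 161 CPM, and the transcription factor gene HAND1, at 101 and 17.9 CPM. The atrial hormone gene NPPA was higher, at 122 and 346 CPM, as was NR2F2, an atrial transcription factor, at 44.7 and 192 CPM. IRX4, which represses atrial genes in ventricular cells, was slightly lower at 105 and 81.1 CPM. The summed level of HEY2, a Notch pathway repressor gene of the ventricular compact wall, did not differ detectably, although it was seen in a smaller share of coculture cells.

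In log2 terms MYL2 stood at -2.58 (-2.74 to -2.42), HAND1 at -2.47 (-2.96 to -2.06), MYH7 at -1.77 (-1.92 to -1.63), IRX4 at -0.38 and HEY2 at -0.13 (-0.32 to 0.05). Of 10 ventricular genes, 4 were at least 1.5-fold lower, 0 higher and 6 between, with a median of -0.36 (-0.49 to -0.29) below all random lists. The mitochondrial share of the class sum, 13.2% in the monoculture and 8.16% in the coculture library, moved with these lists. LBH, a cofactor gene of early heart growth, went the other way within that band, at 223 and 312 CPM. Of 10 atrial genes, 6 were higher, 1 lower and 3 between, with a median of 0.82 (0.66 to 0.95) above all random lists. NR2F2 had a log2 ratio of 2.10, NPPA of 1.51, the calcium channel gene CACNA1D of 0.99 and the limb and heart factor gene TBX5 of 0.64. The abundant atrial chamber genes moved little, with MYL7 at -0.01 and the fast myosin gene MYH6 at 0.32. Of 7 pacemaker genes, 4 were higher and 3 between, with a median of 0.78 (0.51 to 1.03). The sinus node factor gene SHOX2 stood at 6.29 and 90.1 CPM (log2 ratio 3.84) and the pacemaker channel gene HCN4 at 102 and 118 CPM. NPPB, a stress-induced natriuretic peptide gene, stood at only 3.49 CPM in the monoculture library, with a log2 ratio of 1.67 (0.95 to 2.33). With cluster 12 left out, of which NPPA is a leading gene, the log2 ratios of NPPA and NPPB were 0.89 and 0.24. When each cell was assigned by its own markers instead, the ventricular median was -2.13 and the atrial and pacemaker medians turned to -0.63 and -1.02.

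At Leiden resolution 1 the class divided by chamber genes. A cluster led by MYL2, MYH7 and MYL3 held 497 of 823 monoculture and 68 of 142 coculture cells, 60.4% (56.95 to 63.7%) and 47.9% (39.4 to 56.4%). A cluster led by NPPA and TRH held 189 and 65, 23.0% (20.1 to 26.0%) and 45.8% (37.4 to 54.3%). MYL2 stood at 1100 and 267 CPM within the former and NR2F2 at 145 and 353 CPM within the latter. The ventricular and atrial medians were -0.24 (-0.31 to -0.089) and -0.25 (-0.36 to -0.042) in the former and -0.058 (-0.24 to 0.067) and 0.43 (0.29 to 0.63) in the latter. Chamber genes helped to form these clusters, so the medians within them are not independent of the split.

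Shares of cells followed the same order. After thinning, which left out the same 122 and 21 cells, MYL2 was seen in 56.7% of monoculture and 19.5% of coculture cardiomyocyte-like cells, MYH7 in 48.1% and 24.8%, and HAND1 in 31.3% and 9.77%. HEY2 was seen in 38.3% (34.8 to 41.8%) and 23.3% (16.4 to 31.4%), and IRX4 in 37.4% (34.0 to 40.9%) and 27.1% (19.7 to 35.5%). NR2F2 was seen in 12.8% and 39.1% and NPPA in 14.2% and 22.6%. Unthinned shares were 60.6% and 26.6% for MYL2, 59.8% and 39.0% for MYH7, 56.5% and 19.5% for HAND1, 60.02% and 34.4% for HEY2, 62.0% and 42.9% for IRX4, 22.9% and 49.4% for NR2F2, and 20.5% and 29.9% for NPPA. In thinned epicardial-lineage-like cells MYL2 was seen in 0.507% and 0.0379%, MYH7 in 0.663% and 0.0757% and NPPA in 0.156% and 0.0757%. IRX4 was seen in 0.117% and 0.0757% of them and HEY2 in 5.27% and 4.05%. Other heart muscle genes were common there, with MYL7 in 44.1% and 39.9%, TNNT2 in 42.2% and 9.58% and MYH6 in 4.17% and 1.3%. HAND1 and NR2F2 belong to these cells too, and they were seen in 15.3% and 1.87%, and in 39.0% and 47.5%. Median depths before thinning were 19134 and 16287 UMIs in cardiomyocyte-like and 25065 and 22023 UMIs in epicardial-lineage-like cells.

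**Figure D2:**
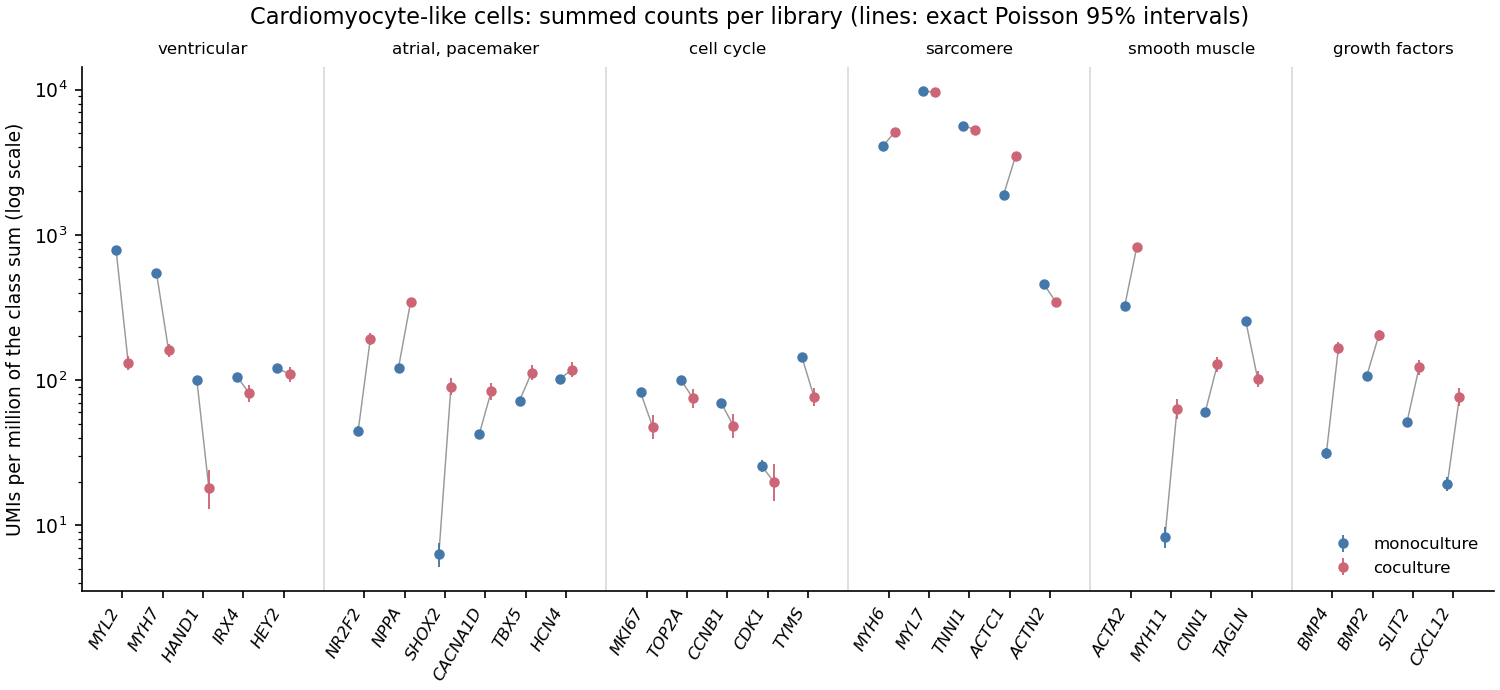
Summed counts of named genes in cardiomyocyte-like cells, in CPM of the class sum (log scale), as pairs of points for the monoculture and coculture libraries with exact Poisson 95% intervals. MYL2 and MYH7 lie lower and NR2F2, NPPA and SHOX2 higher in the coculture library, while MYL7 and TNNI1 lie level.

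Most contractile genes stayed close to level. The troponin genes TNNI1, of the fetal heart, and TNNI3, of the adult heart, had log2 ratios of -0.09 and -0.02, and the Z-disc gene ACTN2 one of -0.41. Cardiac actin ACTC1 was higher, at 1897 and 3511 CPM, as was the intermediate filament gene DES, at 32.3 and 89.2 CPM. Of 27 sarcomere genes, 3 were higher, 3 lower and 21 between, with a median of -0.14 (-0.16 to -0.08). That median was -0.25 over all deposited barcodes and -0.016 with at most 15% mitochondrial UMIs. All 12 calcium handling genes lay between, with a median of 0.03, and so did all 34 oxidative phosphorylation genes, with a median of 0.01. The 14 cardiac transcription factor genes had a median of -0.01, with 3 higher, 2 lower and 9 between, or 1 higher, 2 lower and 11 between relative to all genes of the class. MEF2C, a muscle gene activator, was among the higher ones, at 112 and 175 CPM, and HAND1 among the lower. Ion channel, cell junction, fatty acid oxidation, glycolysis and hypoxia lists had medians of -0.09, -0.08, -0.06, -0.06 and 0.15. Of 14 cholesterol synthesis genes, 3 were lower and 11 between, with a median of -0.33. They include FDPS, at 149 and 99.8 CPM, and MSMO1, at 77.4 and 48.9 CPM, both enzymes of the sterol path.

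Further genes that the fixed rule named in cardiomyocyte-like cells belong to no single list. On the higher side BMP4, a secreted morphogen, stood at 31.2 and 167 CPM (log2 ratio 2.42), the Wnt antagonist gene SFRP1 at 108 and 354 CPM, and ID4, an inhibitor of basic helix-loop-helix factors, at 61.9 and 184 CPM. The chemokine gene CXCL12 stood at 19.3 and 76.6 CPM, the morphogen gene BMP2 at 106 and 203 CPM, the guidance cue gene SLIT2 at 51.5 and 123 CPM and the Notch ligand gene JAG1 at 43.4 and 110.0 CPM. ANGPT1, which stabilises vessels, stood at 49.8 and 134 CPM and FBXO32, an atrophy-linked ubiquitin ligase gene, at 60.6 and 163 CPM. The peroxidase gene PRDX1 stood at 891 and 2249 CPM and the focal adhesion gene TGFB1I1 at 56.2 and 135 CPM. On the lower side were KCTD12, a subunit gene of GABA receptors, at 155 and 60.3 CPM, S100A4, a calcium-binding motility gene, at 674 and 295 CPM, and the nuclear noncoding RNA NEAT1, at 904 and 400.2 CPM. EXTL3, of heparan sulfate synthesis, stood at 107 and 49.3 CPM, the scaffold gene AHNAK at 120.4 and 58.7 CPM and the detoxification gene MGST1 at 138 and 67.6 CPM. APOA1, a transcript of endoderm cells, stood at 183 and 76.2 CPM. Its log2 ratio of -1.26 turned to 0.015 over all deposited barcodes and was -0.12 with doublets kept.

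By fixed lists, 7 of 22 growth factor genes were higher, 1 lower and 14 between, with a median of 0.39 (0.21 to 0.48). Of 6 retinoic acid genes, 4 were higher, with a median of 1.05 (0.81 to 1.11), among them the carrier gene CRABP2, at 128 and 297 CPM. Of 10 mesenchyme genes, 6 were higher and 4 between, or 3 higher and 7 between relative to all genes of the class, with a median of 0.60 (0.35 to 0.70), led among the abundant ones by the growth factor receptor gene PDGFRA, at 68.2 and 136 CPM. Smooth muscle genes had a median of 0.33 (0.24 to 0.37) but divided. Smooth muscle actin ACTA2 stood at 322 and 822 CPM, the myosin gene MYH11 at 8.30 and 63.6 CPM and calponin CNN1 at 60.6 and 128 CPM, while the actin-binding gene TAGLN was lower, at 257 and 101 CPM. The 26 extracellular matrix genes had a median of -0.16, which turned to 0.14 over all deposited barcodes and to 0.084 with doublets kept. The 9 epicardial identity genes had one of -0.07. Targets of TGF-beta, BMP, YAP, Wnt and interferon signalling had medians of 0.45, 0.07, -0.16, 0.32 and -0.03, and immediate early and heat shock genes one of 0.21. The TGF-beta median turned to -0.17 when only members at 50 CPM or more were taken.

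Epicardial-lineage-like cells were compared to see what the partner cells expressed. The complement component gene C3 was higher in the coculture library, at 10.6 and 525 CPM, and so was the protease inhibitor gene SLPI, at 1.76 and 256 CPM. The epicardial transcription factor genes TBX18 and WT1 were lower, at 102 and 29.8 CPM and at 147 and 81.2 CPM. The secreted Wnt modulator SFRP2 was lower too, at 1193 and 85.3 CPM. The class is not 1 population in both libraries. Clusters 5 and 7, led by SHISA3 and SFRP2, held 845 and 795 monoculture cells but 16 and 4 coculture cells. Clusters 1, 2 and 10, led by AKR1B10, HBD and PRG4, held 1917, 1470 and 570 coculture cells but 2, 12 and 4 monoculture cells. A cluster mostly of 1 library may be that library and not a type. SLPI, HBD, CPB1, SPRR2F and ALCAM are among the leading genes of the coculture clusters, and SFRP2, AQP1 and UPK3B among those of a monoculture cluster, so their differences and that division are the same observation.

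Relative to the class median, C3 had a log2 ratio of 5.87 (5.77 to 5.98), the complement protease gene CFB of 6.92, and the initiating protease genes C1R and C1S of 3.82 and 3.03. SLPI stood at 7.42, the stress regulator gene NUPR1 at 4.25 and the globin gene HBD at 4.44. The peptidase gene CPB1 stood at 95.5 and 547 CPM, the cornified envelope gene SPRR2F at 74.1 and 379 CPM, and ALCAM, an adhesion molecule gene, at 30.7 and 154 CPM. Within cluster 8, the cycling cells, which both libraries filled with 300 and 419 cells, C3 stood at 3.73 and 478 CPM and SLPI at 0.454 and 274 CPM. Within the matrix-rich cluster 4, of 222 and 704 cells, C3 stood at 2.78 and 31.4 CPM and SLPI at 0.253 and 0.846 CPM, and in cluster 9, of 430 and 209 cells, SLPI stood at 6.04 and 10.4 CPM. C3 also stood at 0.408 and 25.9 CPM (19.6 to 33.4) in the cardiomyocyte-like cluster 6 and at 3.05 and 17.8 CPM in the endoderm-like cluster 3, so its coculture level in cluster 4 (28.1 to 35.0) was close to that in cardiomyocyte-like cells. In RFP-zero cells alone the unshifted log2 ratio of SLPI was 8.57 against 7.18 over the class.

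On the lower side, SFRP2 had a relative log2 ratio of -3.56 (-3.59 to -3.53), the water channel gene AQP1 of -2.10, the endocytic receptor gene LRP2 of -2.05 and the leptin receptor gene LEPR of -1.90. RAMP1, a receptor partner for calcitonin peptides, stood at 154 and 38.1 CPM and the protocadherin gene PCDH9 at 107 and 29.2 CPM. The LIM protein genes CRIP1 and CSRP2 stood at 457 and 144 CPM and at 381 and 125 CPM. The kinase gene STK26 stood at 149.95 and 47.8 CPM and ODC1, of polyamine synthesis, at 193 and 67.2 CPM. HAND1, a mesodermal factor, was lower here too, at 57.9 and 3.98 CPM.

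Of 19 epicardial identity genes, 9 were lower than the class median by at least 1.5-fold, 1 was higher and 9 lay between, with a relative median of -0.38 (-0.43 to -0.36). Without the shift the split was 11 lower, 1 higher and 7 between. TBX18 had a relative log2 ratio of -1.54, the fibroblast fate gene TCF21 of -0.70, WT1 of -0.61, the retinoic acid synthesis gene ALDH1A2 of -0.38, the basonuclin gene BNC1 of -0.23, the keratin gene KRT19 of -0.17 and the mesothelial gene UPK3B of -1.52. After thinning, WT1 was seen in 48.5% and 32.5% of epicardial-lineage-like cells against 0.510% and 0.114% of endoderm-like cells, and TBX18 in 30.9% and 10.5% against 2.81% and 4.56%. Thinning left out 46 and 26 epicardial-lineage-like cells, and unthinned shares were 85.0% and 73.0% for WT1 and 60% and 30.6% for TBX18. In cluster 9, which is mostly RFP-positive, TBX18 stood at 146 and 122 CPM and WT1 at 71.2 and 84.8 CPM. In cluster 8 they stood at 69.2 and 21.7 CPM and at 138 and 73.9 CPM, and in cluster 4 at 9.35 and 5.55 CPM and at 103 and 75.96 CPM, so WT1 was lower within clusters 8 and 4 but not within cluster 9. In cells assigned by their own markers the list's median turned to 0.24.

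Matrix genes divided. The fibrillar collagen gene COL3A1 was higher, at 1943 and 2887 CPM, as were the small proteoglycan gene DCN, at 799 and 1655 CPM, and POSTN, a matricellular gene of activated fibroblasts, at 136 and 350 CPM. The basement membrane genes LAMC1 and NID2 were lower, at 313 and 117 CPM and at 53.4 and 15.8 CPM. COL1A1, of the main fibrillar collagen, stood at 1736 and 1580 CPM. Of 31 matrix genes, 9 were higher, 4 lower and 18 between relative to the class median, with a relative median of 0.11 (0.07 to 0.12) at percentile 83.3. Without the shift the split was 4 higher, 5 lower and 22 between. Fibronectin FN1 stood at 511 and 364 CPM over the class, but its unshifted log2 ratio was 0.94 in RFP-zero cells alone. The matrix list's unshifted median in those cells was 0.28.

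In epicardial-lineage-like cells 21 of 49 G2/M genes were lower in the coculture library relative to the class median, 0 were higher and 28 lay between, with a relative median of -0.49 (-0.53 to -0.46). Without the shift, 38 were lower and 11 between. MKI67 stood at 69.2 and 34.8 CPM, TOP2A at 95.5 and 52.7 CPM, the kinetochore gene CENPF at 145 and 56.8 CPM and CCNB1 at 65.3 and 32.3 CPM. Core mitotic and S phase genes had relative medians of -0.60 and -0.25, and cell cycle inhibitors one of 0.10. After thinning, 16.6% and 10.1% of cells held at least 2 core mitotic transcripts, and without thinning 36.9% and 23.7%. With the cycling cluster left out, unshifted log2 ratios were -1.58 for MKI67 and -1.54 for TOP2A, against -0.99 and -0.86 over the class.

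Immediate early and heat shock genes were higher, with 8 of 12 higher, 1 lower and a relative median of 0.96. FOS and JUNB, transcription factor genes switched on within minutes of a stimulus, stood at 41.5 and 259 CPM and at 20.7 and 60.04 CPM, with JUN at 103 and 179 CPM and IER2 at 44.5 and 73.4 CPM. The unshifted log2 ratio of FOS was 2.64 over the class and 4.32 in RFP-zero cells. BMP targets had a relative median of 0.67, with ID1 at 415 and 677 CPM and ID3 at 577 and 773 CPM, and interferon genes one of 0.47. The antiviral tether gene BST2 stood at 191 and 523 CPM and the membrane gene IFITM3 at 1298 and 1589 CPM. ISG15 and IFI6 went the other way, at 89.3 and 44.1 CPM and at 105 and 61.1 CPM, but turned to unshifted log2 ratios of 0.30 and 0.80 in RFP-zero cells. In cluster 9 ISG15 stood at 301 and 63.9 CPM.

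Growth factor genes had a relative median of 0.28, with 6 higher, 5 lower and 12 between. Midkine MDK and TGFB2, which are heparin-binding and TGF-beta ligands, were lower, at 1279 and 599 CPM and at 99.0 and 51.2 CPM, and IGF2, a fetal mitogen, stood level at 126 and 103 CPM. TGF-beta targets had a relative median of 0.35, mesenchyme genes one of 0.18 and YAP targets one of -0.20, although the YAP targets CCN1 and CCN2 were higher, at 117 and 223 CPM and at 156 and 231 CPM. When only members at 50 CPM or more were taken, the unshifted YAP median turned from -0.45 to 0.57 and the unshifted TGF-beta median from 0.10 to -0.17. The cadherin gene CDH11 was lower, at 168 and 77.2 CPM, and the mural receptor gene PDGFRB stood at 39.1 and 51.0 CPM. Smooth muscle genes had a relative median of -0.40, with ACTA2 at 65.8 and 16.7 CPM (unshifted log2 ratio -1.98, or -1.26 in RFP-zero cells), TAGLN at 208 and 68.1 CPM and MYL9 at 604 and 336 CPM. Cholesterol synthesis, p53 and Wnt target lists had relative medians of -0.37, -0.34 and -0.49, with HMGCS1 at 86.6 and 44.0 CPM and SQLE at 120.02 and 75.8 CPM. Cell junction, glycolysis, oxidative phosphorylation, fatty acid oxidation, hypoxia and retinoic acid lists had relative medians of -0.21, -0.05, 0.03, 0.14, 0.10 and -0.14.

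Heart muscle transcripts in epicardial-lineage-like cells were mostly lower in the coculture library. The fall was not particular to them. In endoderm-like cells 8 of 10 sarcomere genes were lower and 0 higher, with a median of -1.68 relative to that class. TNNT2 was seen in 7.40% and 2.28% of thinned endoderm-like cells. Values below are those of epicardial-lineage-like cells unless named otherwise. Troponin T TNNT2 stood at 157 and 29.1 CPM and titin TTN at 87.5 and 8.97 CPM. Of 13 sarcomere genes, 10 were lower, 1 higher and 2 between, with a relative median of -1.38, while ventricular, atrial and pacemaker lists had relative medians of -0.41, -0.72 and -1.06. Cardiac transcription factor, calcium handling and ion channel lists had relative medians of -0.37, -0.64 and -0.25. The unshifted calcium handling median was -0.88, or -0.30 in RFP-zero cells, and the unshifted ventricular one -0.65, or -1.30 over all members with a count. Free RNA was estimated at 1.43% and 1.35% of these sums and at 4.46% and 3.19% of the cardiomyocyte-like sums. With it subtracted the unshifted sarcomere median went from -1.62 to -1.15.

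**Figure D3:**
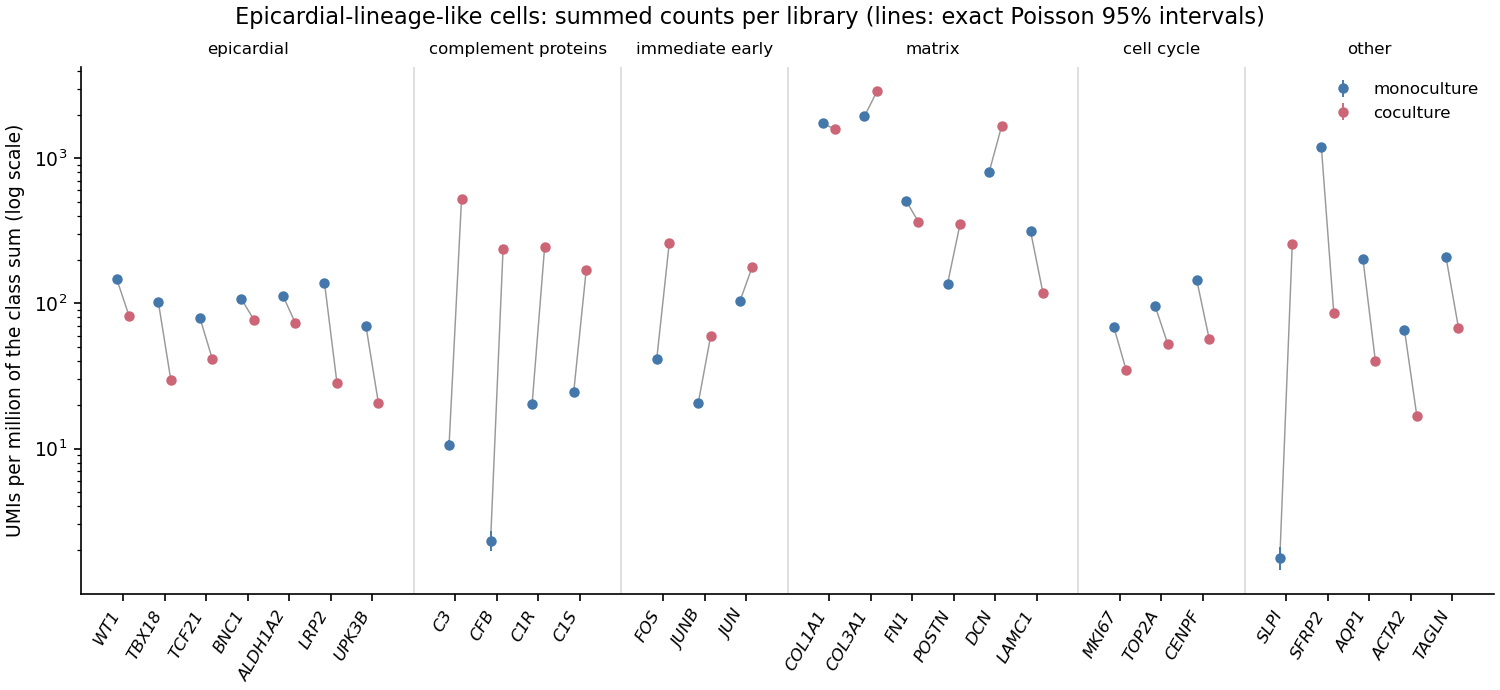
Summed counts of named genes in epicardial-lineage-like cells, in CPM of the class sum (log scale), as pairs of points for the monoculture and coculture libraries with exact Poisson 95% intervals. C3, CFB and SLPI lie higher and SFRP2, TBX18 and WT1 lower in the coculture library.

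Endoderm-like cells were present in both libraries and mostly RFP-positive, with 795 and 896 cells, and cluster 3 held most of them in each, 77.9% and 78.2%. The make-up of the rest differed. Cluster 11, led by AHSG, held 17.2% of the monoculture and 10.9% of the coculture cells of the class, and cluster 13 held 4.91% and 10.8%. At Leiden resolution 1, cluster 23, with CALB1 among its leading genes, held 0 monoculture and 52 coculture cells. Differences over the class may therefore reflect its make-up as well as expression within cells. Of 52 G2/M genes, 8 were at least 1.5-fold higher in the coculture library, 0 lower and 44 between, with a median of 0.36 (0.33 to 0.41), and 51 had a log2 ratio above 0. Of 10 core mitotic genes 1 was higher and 9 lay between, with a median of 0.49. MKI67 stood at 60.9 and 88.2 CPM, CENPF at 94.3 and 142 CPM and UBE2C, which tags mitotic proteins for degradation, at 157 and 221 CPM. Within cluster 3 MKI67 stood at 78.4 and 109 CPM, within cluster 11 at 15.3 and 18.7 CPM and within cluster 13 at 27.2 and 27.3 CPM. After thinning, 27.4% of monoculture and 25.7% of coculture cells held at least 2 core mitotic transcripts, with 11 and 19 shallower cells left out, and 54.8% and 52.9% without thinning. The S phase median was 0.02.

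Among the other genes named in endoderm-like cells, the calcium buffer gene CALB1 stood at 10.1 and 138 CPM, the iron hormone gene HAMP at 94.1 and 241 CPM, the trypsin inhibitor gene SPINK1 at 200.4 and 442 CPM, fibrinogen FGG at 437 and 749 CPM and the liver factor gene CEBPA at 61.8 and 101 CPM. Lower were the neuropeptide gene CARTPT, at 107 and 12.9 CPM (log2 ratio -3.04, or -2.34 with doublets kept), the plasma protein gene AHSG, at 1521 and 426 CPM, the thyroid hormone carrier TTR, at 6554 and 2612 CPM, the apolipoprotein APOA2, at 5158 and 2163 CPM, and DLK1, a progenitor gene, at 616 and 199 CPM. AHSG is a leading gene of cluster 11, whose share of the class was lower in the coculture library. How much of the differences of these genes comes from the make-up of the class was not tested. The p53 targets had a median of -0.74, among them the stress cytokine GDF15, at 231 and 92.6 CPM. Cholesterol synthesis had a median of -0.50, glycolysis one of -0.32 and BMP targets one of 0.27.

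**Figure D4:**
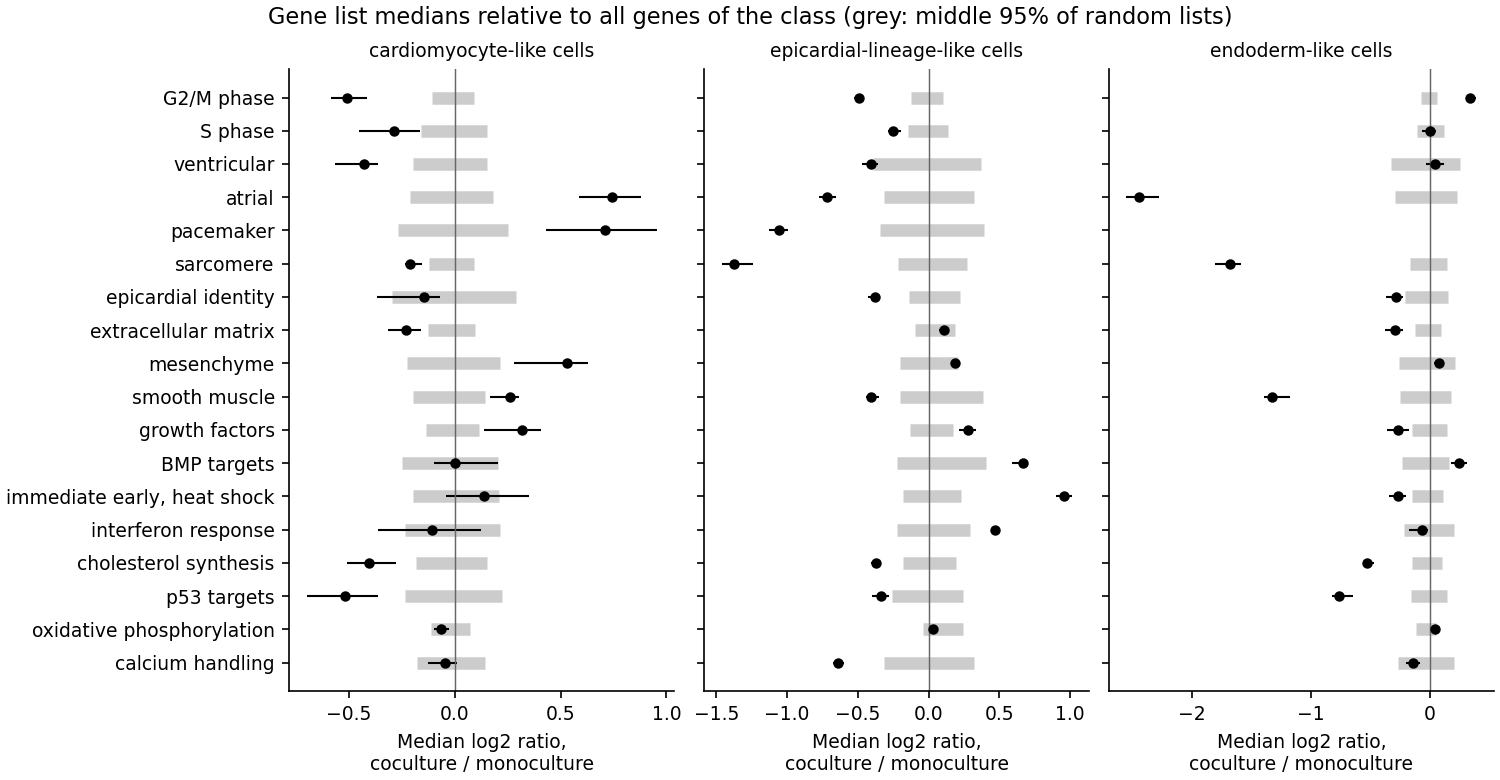
Median log2 ratio of coculture over monoculture for fixed gene lists in each class, relative to all genes of the class (points with counting intervals; grey bars hold the middle 95% of random lists; horizontal scales differ between classes). The G2/M list lies below the grey bar in cardiomyocyte-like and epicardial-lineage-like cells and above it in endoderm-like cells.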

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

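The tests chosen only after the result was seen are those on endoderm-like cells, on RFP-positive cells and without cluster 12. So are the tests on barcodes put back with unnamed clusters added, and the use of the planned thinned difference against depth. The run over all deposited barcodes was chosen beforehand. Several gene lists stood above nearly all random lists in one class of cells and below nearly all in another. With 1 library per group these differences between classes were not tested. All medians here are log2 ratios of coculture over monoculture relative to all genes of the class. The G2/M median was 0.34 in endoderm-like cells but -0.51 in cardiomyocyte-like and -0.49 in epicardial-lineage-like cells, and core mitotic genes had medians of 0.47, -0.65 and -0.60 in the same order. Immediate early and heat shock genes had medians of 0.96 in epicardial-lineage-like and -0.27 in endoderm-like cells. Smooth muscle genes had medians of 0.26 in cardiomyocyte-like, -0.40 in epicardial-lineage-like and -1.33 in endoderm-like cells. The endoderm-like value was not itself flagged, as the list's total was low there beside the class with most of it. ACTA2 was seen in 3.83% and 1.60% of thinned endoderm-like cells and TAGLN in 14.9% and 1.82%. Growth factor genes had medians of 0.32 in cardiomyocyte-like and 0.28 in epicardial-lineage-like cells but -0.27 in endoderm-like cells. TGF-beta targets had medians of 0.35 in epicardial-lineage-like and -0.43 in endoderm-like cells. The former rests on 6 measured members at percentile 97.6. Its unshifted value turned from 0.10 to -0.17 when only members at 50 CPM or more were taken.

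For the lower mitotic genes, a shift of the whole coculture library, such as depth or preparation, is argued against by the endoderm-like cells, whose unshifted G2/M median was 0.36 (0.33 to 0.41) and whose thinned share with core mitotic transcripts did not differ detectably, at 27.4% (24.3 to 30.7%) and 25.7% (22.8 to 28.7%). Depth per cell as the whole cause is argued against by the thinned difference of -12.8 percentage points (-17.5 to -6.51) in cardiomyocyte-like cells with core mitotic transcripts. That difference rests on 133 coculture cells, and its interval includes 0 over all deposited barcodes and, at -3.99 points (-7.89 to 1.85), with the MKI67-rich cluster 12 left out. With marked doublets kept it was -7.58 points (-12.8 to -1.10). What stays open and untested is that cycling cells were lost selectively at dissociation or gating, and that contact between the cells lowered their cycling. Exchanged library labels stay open too, as these lists run against the direction that the series title gives for cardiomyocytes, and an exchange would turn every direction given here.

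The share of cardiomyocyte-like cells was lower in the coculture library. As the whole cause, dilution by epicardial-lineage-like cells, through mixing or growth, would leave the share among RFP-positive cells level. Yet that share was 12.9% (10.97 to 15.1%) against 38.8%. Dilution as a part of the cause stays open, as RFP-positive cells made up 42.5% of the monoculture and 16.7% of the coculture cells used. Barcodes lost at the filters are argued against by putting all of them back, unnamed low-depth clusters with mostly cardiomyocyte markers included, where 1549 of 5464 and 275 of 7142 barcodes made the monoculture share 7.36 times the coculture share. Different survival, different recovery after dissociation, and more endoderm-like cells in that culture from its start stay open and were not tested.

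The GFP feature, which no comparison uses, had 49 UMIs in the monoculture and 48 in the coculture library over all barcodes. Both lay above the floor of 3 counts used here. If the GFP feature reads the eGFP line, whose cells hold no RFP UMIs, its UMIs should lie in RFP-zero cells. They did for 100% (92.3 to 100%) of the 46 UMIs in coculture cells used, where RFP-zero cells held 74.5% of all UMIs, and for 89.4% (76.9 to 96.5%) of the 47 in monoculture cells used, where they held 44.7%. The feature may therefore come from the eGFP line, at a level too low to mark cells.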

How the results depend on the processing

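All values here are unshifted, and assignment by RFP, the adding of unnamed clusters and the removals of shallow cells, of the low-UMI cluster and of the cycling clusters were chosen after seeing the data. The main comparisons gave 67 alternative values within counting error of the main one, 42 that moved beyond it and 1 that reversed. For the other results named in the text the numbers were 1670, 617 and 35. Some values counted as moved also changed sign, so the reversed ones are not all changes of direction. Among the main comparisons these were matrix medians of epicardial-lineage-like cells. They went from -0.14 to 0.28 in RFP-zero cells, 0.11 with median-ratio scaling and 0.0086 with the mean of single-cell CPM. No paired analysis was possible because each group has 1 library.

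In cardiomyocyte-like cells the G2/M median ranged from -0.62 to -0.12, the ventricular median from -2.13 to -0.31 and the sarcomere median from -1.85 to -0.016, with no change of direction in any alternative run. The mitotic difference ranged from -15.7 to -3.99 percentage points. The cardiomyocyte-like share ranged from 14.0 to 81.9% in the monoculture and from 2.10 to 34.5% in the coculture library. The upper ends come from assignment by own markers, whose scaling sets much of them. In epicardial-lineage-like cells the G2/M median ranged from -0.77 to -0.46.

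Assigning each cell by its own markers moved most. It gave cardiomyocyte-like shares of 81.9% and 34.5%, medians of -2.13 (ventricular) and -1.85 (sarcomere), and a mitotic difference of -6.11 points. In cardiomyocyte-like cells it reversed the atrial (-0.63), pacemaker (-1.02) and retinoic acid (-0.075) medians and NPPA (-0.44), NPPB (-1.99), BMP4 (-0.028), ANGPT1 (-0.29), ACTA2 (-0.90), JAG1 (-0.50), PRDX1 (-0.43), SLIT2 (-0.26), CACNA1D (-0.55), TBX5 (-0.63), CNN1 (-0.62), CRABP2 (-0.019), BMP2 (-1.22), ACTC1 (-1.05) and MEF2C (-1.03). In epicardial-lineage-like cells it reversed the epicardial identity (0.24), pacemaker (0.29), immediate early (-0.24) and smooth muscle (0.0011) medians and WT1 (0.15), TBX18 (0.29), ALDH1A2 (2.29), PCDH9 (0.024), CRIP1 (0.72), IER2 (-0.41), IFI6 (0.32), UPK3B (0.70), TGFB2 (0.052) and MYL9 (0.18). Its cardiomyocyte-like cells were 58.4% and 77.0% epicardial-lineage-like by clusters, so it compared other cells.

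Over all deposited barcodes the monoculture share was 17.3%, the G2/M median of cardiomyocyte-like cells -0.55, the sarcomere median -0.25 and the mitotic difference -6.46 points (-11.8 to 0.23), and APOA1 reversed to 0.015. The class there, with marked doublets put back too, held 943 and 158 barcodes, 106 and 2 of which fail the filters. With unnamed clusters of mostly cardiomyocyte markers added it held 1549 and 275, 603 and 92 of which fail them, and the shares were 28.3% and 3.85%, the G2/M median -0.53, the sarcomere median -0.24, APOA1 0.071 and the mitotic difference -5.00 points (-10.01 to 1.19). With at most 15% mitochondrial UMIs the monoculture share was 14.0% and the sarcomere median -0.016. With doublets kept the mitotic difference was -7.58 points (-12.8 to -1.10), the G2/M median -0.61 and the sarcomere median -0.21. With the mean of single-cell CPM the G2/M and sarcomere medians were -0.62 and -0.047, and with median-ratio scaling the sarcomere median was -0.21. Without cells under 5000 UMIs the monoculture share was 18.3%, and at Leiden resolution 1 it was 18.5%. With assignment by RFP the sarcomere median was -0.17. Leaving out the cycling cluster 12, which removes the cells with most MKI67 by construction, gave a G2/M median of -0.12, a sarcomere median of -0.17 and a mitotic difference of -3.99 points (-7.89 to 1.85). For the others the cause was not tested.

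In epicardial-lineage-like cells the main unshifted medians were -0.74 (G2/M), -0.63 (epicardial identity) and -0.14 (matrix). Median-ratio scaling, which removes the class shift by construction, gave -0.49, -0.38 and 0.11. Leiden resolution 1 gave -0.70, -0.61 and -0.11, and the mean of single-cell CPM gave -0.70, -0.72 and 0.0086. Members at 50 CPM or more gave -0.65 for G2/M and -0.054 for matrix. Leaving out the cycling cluster gave -0.46 for G2/M and -0.60 for epicardial identity. RFP-zero cells alone gave -0.75 for epicardial identity and 0.28 for matrix, and reversed ISG15 to 0.30 and IFI6 to 0.80. The cause was not tested. The 154 coculture cardiomyocyte-like cells and their 2.45 M UMIs limit the precision of that comparison, beside the lack of replicates.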

Other observations

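Clustering at Leiden resolution 1 was an alternative chosen beforehand. Every other test weighed in this part was chosen only after the result was seen. Beside the main classes, cluster 14 held 91 monoculture cells, 2.05% (1.65 to 2.51%), and 21 coculture cells, 0.326% (0.202 to 0.499%). Its leading genes include the GABA receptor subunit gene GABRP at 441 and 430 CPM, the immune checkpoint gene VTCN1 at 279 and 210 CPM and the transcription factor gene TFAP2A at 224 and 168 CPM. Its cells were RFP-positive in 80.2% and 71.4% of cases, and it stayed unnamed because its 10 leading genes held 0 epicardial-lineage markers, although 14 were higher over the cluster, against 1 of another class. Cluster 16, with 19 and 49 cells at median depths of 3554 and 4044 UMIs, stayed unnamed too. The 29 monoculture endothelial-like cells held EGFL7 at 1342 CPM and KDR at 566 CPM.

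Cluster 9 of the epicardial-lineage-like class was RFP-positive in 90.7% of 430 monoculture and 78.0% of 209 coculture cells, so it traces to the cardiac line. In it C3 stood at 4.66 and 44.1 CPM (37.7 to 51.3), against 478 CPM in coculture cells of cluster 8 and 25.9 CPM (19.6 to 33.4) in those of the cardiomyocyte-like cluster 6. The p53 target and cholesterol synthesis lists were lower in the coculture library in all 3 large classes, at -0.44 and -0.33 in cardiomyocyte-like, -0.74 and -0.50 in endoderm-like and, relative to the class median, -0.34 and -0.37 in epicardial-lineage-like cells.

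A hypothesis from these values is that the cardiomyocyte-like cells of the coculture library differ in subtype, with more atrial or pacemaker character, and not only in level. The atrial median lay 1.17 (0.999 to 1.37) above the ventricular one in log2 terms. Loss of barcodes at the filters is argued against by the same difference with all barcodes of cardiomyocyte clusters put back, named or not, and each weighted alike, 1.12 (0.761 to 1.60). For the 603 and 92 of these that fail the filters, taken alone, it was 1.11 (0.419 to 2.05). At Leiden resolution 1 the class splits along this line. The cluster led by MYL2 held 60.4% (56.95 to 63.7%) of 823 monoculture and 47.9% (39.4 to 56.4%) of 142 coculture cells, and the one led by NPPA 23.0% (20.1 to 26.0%) and 45.8% (37.4 to 54.3%). Within these clusters the reading is mixed, with atrial medians of -0.25 (-0.36 to -0.042) in the former and 0.43 (0.29 to 0.63) in the latter and ventricular medians of -0.24 (-0.31 to -0.089) and -0.058 (-0.24 to 0.067), and chamber genes helped to form the clusters. For RNA from epicardial-lineage-like cells, 6 atrial members picked as little held by those cells had a median of 0.16. They were NPPA at 1.51, CACNA1D at 0.99, MYH6 at 0.32, MYL7 at -0.01, MYL4 at -0.15 and GJA5 at -0.92. MYL7 was nevertheless seen in 44.1% of monoculture and 39.9% of coculture epicardial-lineage-like cells after thinning. The median of 0.16 lies within the random-list range of the full atrial list, -0.14 to 0.25. The observed atrial median of 0.82 therefore leans on members outside this set, and the test did not settle the source of their RNA. A mixing test was then chosen after that result. At the average profile of the class, epicardial-lineage-like RNA could make up at most 3.37% of the coculture cardiomyocyte-like sum, a limit set by DCN. That share would give an atrial median of -0.049 where 0.82 was observed. RNA from a single cluster low in DCN was not bounded, and the pacemaker median was tested in neither way.

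Exchanged labels cannot be told apart from the labelled order, because the difference of 1.17 would keep its size and turn its sign, and the labels name no transcript that only 1 condition can hold. The series title states more cardiomyocyte proliferation and ventricular identity in coculture, and the lower G2/M and ventricular lists run the other way, which is what raises the question. An exchange would turn every other direction given here as well. Selective survival or recovery of cardiomyocyte subtypes, a different make-up of the cultures at the start, and a response to contact may each give the same values, and these were not tested. Several cultures per group, with MYL2, MYH7, NR2F2 and NPPA stained in RFP-positive cells, could show whether the difference recurs but not which of these causes it. Counting the same cells at the start and following their survival through culture and dissociation could help to tell them apart.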
